A study of Mus musculus with 12 samples.

How the data were processed

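The 12 samples were libraries of adipocytes and stromal vascular cells (SVCs) of epididymal (EAT) and inguinal (IAT) adipose tissue from mice on a high-fat diet, with 3 libraries per group. Groups and replicate numbers were taken from the samples' labels. No label says that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

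The deposited tables hold RSEM expected counts, TPM and FPKM per gene, with gene length and effective length, per the file headers. The submitters' processing notes name RSEM 1.2.25, Bowtie2 2.2.6 and limma, and the genome builds GRCm38 and mm10, without saying which step used which. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes, and genes that share reads with near-identical copies, are uncertain. RSEM's estimated counts need not be whole, and the deposited values were used as they stand apart from rounding. The deposited TPM values were used only to weight effective lengths, and the deposited FPKM values were not used in tests.

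Each table lists 32182 genes, of which 19419 have 1 transcript and 12763 several. Genes are given as a running number (1 to 32408) and UCSC transcript identifiers. The files do not pair these with gene symbols, and no table used here does. The 32 gene lists fixed before the data were examined (markers of cell types and pathways), the symbol-based parts of the rule for named genes, and the alternative that leaves out mitochondrially encoded genes were therefore not analysed here. The rule for named genes was, per comparison, the genes with the largest positive and negative log2 fold changes among those with an adjusted p below 0.05, a mean of at least 10 CPM in the higher group and no overlap between the replicates of the 2 groups. Of these, only the first 2 in each direction of the depot difference in adipocytes are named.

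Expected counts were rounded to whole numbers. Libraries were scaled with TMM, genes with low counts were removed with filterByExpr (15813 genes kept, holding at least 99.9% of the counts of each library), and all 12 libraries were fitted together with 1 coefficient per group, which leaves 8 residual degrees of freedom. Differences were tested, two-sided, with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) and Benjamini-Hochberg adjustment over genes in each of 5 comparisons, at 0.05. Standard errors were taken as the size of the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. The common biological coefficient of variation was 0.195. Sets of genes were tested with camera (limma 3.58.1), adjusted over the 2 classes tested in each comparison.

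Depth was 20707325 to 26349357 expected counts, so 3 counts correspond to 0.105 to 0.158 CPM in a single library. Shares carry exact binomial intervals at 95%, which treat genes as independent and leave out the spread between libraries.

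The pipeline was tested on simulated negative binomial counts with the real means, library sizes and dispersions of 15813 genes, of which 100 were changed 2-fold and 100 changed 4-fold in 1 group. For the depot difference in adipocytes, 56% of the 2-fold and 92% of the 4-fold changes were recovered by edgeR. The shares were 54% and 96% for the depot difference in SVCs, 50% and 93% for the fraction difference in EAT, 54% and 87% for that in IAT, and 23% and 78% for the interaction. Of edgeR's calls, 3.38% to 6.62% were false over these comparisons, and of DESeq2's 9.09% to 20.4%. These simulations hold no library that stands apart. Each gene had 1 mean for all groups, so no gene other than the changed ones differed between groups. Far more genes were called in the real data, so the recovered shares may not carry over to it.

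Replicate numbers 1 to 3 recur in every group. Deviations from the group means of same-numbered libraries correlated at 0.199, 0.121 and 0.189 between IAT adipocytes and IAT SVCs, and at 0.166, 0.134 and 0.131 between EAT SVCs and IAT SVCs, each above 0.1. In the other pairs of groups at least 1 number fell below 0.1. The numbers may therefore pair the samples in the IAT fraction difference and in the SVC depot difference, as judged from the data alone. The main tests did not use this pairing. A block for the replicate number was fitted only as an alternative.

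Alternatives fixed before the data were examined were DESeq2's size factors, library size alone, no filter, DESeq2 1.42.0, limma-voom, a fit to only the libraries of the 2 groups, the replicate number as a block, a 2-fold definition of SVC genes, and leaving out each library in turn. Alternatives chosen after seeing the data were limma-voom with library weights, removal of each library's trend with gene length, removal of the 10 genes with the most counts, and fits to the libraries of 2 groups with the block or without EAT adipocyte replicate 2.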

Results

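RNA was sequenced from cell fractions of white adipose tissue of male C57BL/6J mice, an inbred laboratory strain, that received a high-fat diet for 10 weeks from the age of 8 weeks. Epididymal adipose tissue (EAT) is a visceral fat depot of the abdomen, and inguinal adipose tissue (IAT) is a subcutaneous one. Each depot had been digested with collagenase into adipocytes, the lipid-storing cells, and stromal vascular cells (SVCs), the mixed remainder that holds among others precursor, immune and endothelial cells. The 4 groups of 3 libraries were EAT adipocytes, IAT adipocytes, EAT SVCs and IAT SVCs. The 12 libraries held between 20707325 and 26349357 expected counts. A count was seen for 17598 to 17888 genes in the adipocyte libraries and for 18633 to 19161 genes in the SVC libraries. The 10 most abundant genes took 13.4% ± 1.33 (SD, n = 3) of the counts in IAT adipocytes, 8.84% ± 0.748 in EAT adipocytes, 7.85% ± 0.410 in IAT SVCs and 7.12% ± 0.676 in EAT SVCs.

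The first principal component of log2 CPM, the count scaled to the library size, held 68.7% of the variance and separated adipocytes from SVCs. The second held 14.9% and separated EAT from IAT in both fractions. Replicate libraries of the same group correlated across genes at r of 0.984 or higher, except that EAT adipocyte replicate 2 reached 0.950 and 0.953 with replicates 1 and 3, which correlated with each other at 0.987. Genes are not independent replicates, so these coefficients describe the libraries. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom was at least 12.5 for every pair of replicates.

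**Figure D1:**
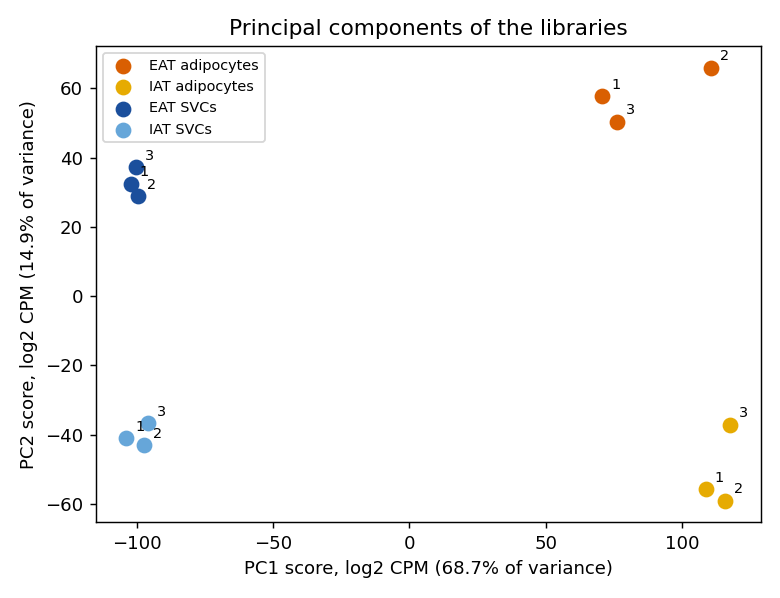
Scores of the 12 libraries on the first 2 principal components of log2 CPM, coloured by group and numbered by replicate. Adipocytes lie to the right and SVCs to the left (68.7% of the variance), and EAT lies above IAT (14.9%).

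The comparison of adipocytes with SVCs asks which genes distinguish the fractions within a depot. In EAT, 4815 genes were higher in adipocytes and 5061 were higher in SVCs, of 15813 tested. In IAT, 4669 genes were higher in adipocytes and 6401 in SVCs. With DESeq2's size factors in place of TMM these counts were 5094 and 4878 in EAT, where the balance turned, and 5222 and 5651 in IAT. With library size alone they were 3896 and 5841 in EAT and 3827 and 7488 in IAT. With only the 6 libraries of a depot they were 4051 and 3929 in EAT and 5976 and 5936 in IAT, so that the balance turned in both. At least 4-fold differences were found for 753 genes higher in adipocytes and 1785 higher in SVCs in EAT, and for 1241 and 2238 genes in IAT. The fractions differed alike in both depots: 3701 genes were higher in adipocytes in both depots, against 1422 for independent lists, and 4161 were higher in SVCs in both, against 2049. Of the 8180 genes called in both depots, 96.1% went the same way, and the log2 fold changes correlated across genes at r = 0.847. These 2 comparisons share no library, but the joint fit gave each gene the same spread in both, so their calls are not independent. These calls are from edgeR's quasi-likelihood test at an adjusted p below 0.05. In EAT, 10 genes reached 1 CPM in all 3 adipocyte libraries with no count in any SVC library, and in IAT 15 genes did so; in each depot 1 gene did the reverse. An exact two-sided permutation test of a single gene in 3 against 3 libraries cannot go below p = 0.1.

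To describe the depots by kind of cell, 956 "adipocyte genes" and 1880 "SVC genes" were taken as those at least 4-fold higher in one fraction than in the other (adjusted p below 0.05, edgeR) in the mean over both depots. The remaining 12977 tested genes are called other genes. In every alternative that reports on classes, they were drawn anew from that fit, so their members changed along with the calls. These classes were chosen on the same libraries, so they are not independent evidence about a fraction, but the mean over depots is a contrast orthogonal to each depot difference when all groups have the same spread. That condition was not met. The chi-square per degree of freedom reached 171 between EAT adipocyte replicates, against at most 48.4 in the other groups. The choice of classes and the depot difference in adipocytes may therefore be correlated.

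The comparison of EAT with IAT adipocytes asks how the lipid-storing cells of the 2 depots differ. More adipocyte genes were lower than higher in EAT: 494 of 956 were lower, 22 were higher and 440 did not pass the test. With the class drawn anew, the 22 became 12 without IAT adipocyte replicate 2 and 40 of 1084 without EAT adipocyte replicate 1. Their median log2 difference was -0.71 (quartiles -1.16 and -0.25). As a set they stood below all other genes (camera, preset inter-gene correlation of 0.01, adjusted p = 1.19e-21), but not with an estimated correlation (adjusted p = 0.112). The SVC genes were split, with 252 higher and 274 lower of 1880, a median of 0.02 and a camera adjusted p of 0.543. Of the other genes, 3140 were higher and 2101 lower in EAT. In all, 6283 of 15813 genes differed, 3414 higher and 2869 lower in EAT, of which 666 and 256 were at least 4-fold apart. With DESeq2's size factors in place of TMM the balance turned, to 2814 higher and 3717 lower. Fitted to the 6 adipocyte libraries alone, 4056 genes passed.

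SVC genes made up 7.38% of the genes higher in EAT adipocytes (252 of 3414, 95% exact binomial interval 6.53% to 8.31%), 9.55% of those lower (8.50% to 10.7%) and 11.9% of all genes tested. Genes are not independent, and these intervals leave out the spread between libraries, so they are too narrow. With SVC genes defined at 2-fold, these shares were 22.8%, 19.3% and 24.4%, so that the order of the higher and lower genes turned. It also turned without IAT adipocyte replicate 1, to 8.18% and 8.02%.

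**Figure D2:**
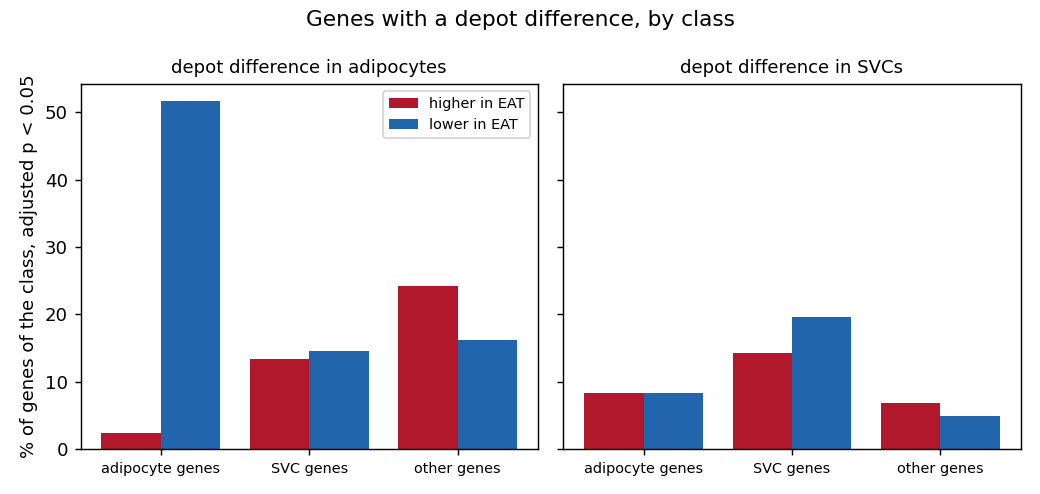
Percentage of the adipocyte, SVC and other genes that were higher (red) or lower (blue) in EAT than in IAT at an adjusted p below 0.05, in adipocytes (left) and SVCs (right). Of the adipocyte genes, 51.7% were lower and 2.30% higher in EAT adipocytes, while 8.37% were lower and 8.37% higher in EAT SVCs.

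The files pair genes with UCSC transcript identifiers and with no gene symbol, so single genes are given by identifier. The gene uc009tsq.1 (2 transcripts) had 14.4 ± 2.62 CPM (SD, n = 3) in EAT adipocytes and no count in any IAT adipocyte library, at least 303-fold higher against a floor of 3 counts over the group. It was the only tested gene that reached 1 CPM in all 3 EAT adipocyte libraries and had no count in the 3 IAT adipocyte libraries. In SVCs it had 282 counts in EAT and 2 in IAT, a ratio of 132 with a counting interval of 36.5 to 1089 at 95%. The gene uc029xfx.1, an SVC gene with 1 transcript, had 52.6 ± 29.9 CPM in EAT adipocytes and 0.995 ± 0.316 in IAT adipocytes, a log2 difference of 5.71 (SE 0.56, adjusted p = 1.23e-05, edgeR), higher in all 3 libraries. In SVCs its levels were 849 ± 188 and 14.6 ± 6.97 CPM, a log2 difference of 5.86 (SE 0.52). The depot by fraction interaction of this gene did not pass (log2 -0.15, adjusted p = 0.922, edgeR). Whether its RNA in the adipocyte fraction came from adipocytes was not tested. The gene uc008qql.1 had 4 counts over the 3 EAT adipocyte libraries and 18.0 ± 2.36 CPM in IAT adipocytes, a log2 difference of -8.00 (SE 0.36, adjusted p = 1.96e-07, edgeR). It was -9.26 without EAT adipocyte replicate 1 and -7.38 without replicate 3, and the ratio of the summed counts was 277, with a counting interval of 108 to 1017 at 95%. In SVCs it had 7 counts in EAT and 39.7 ± 5.37 CPM in IAT, a log2 difference of -8.69 (SE 0.33). The gene uc008plc.1 had 0.331 ± 0.102 CPM in EAT adipocytes and 22.3 ± 1.65 in IAT adipocytes, a log2 difference of -6.08 (SE 0.22, adjusted p = 3.49e-08, edgeR), and 93 counts over the 3 EAT SVC libraries against 916 over the 3 IAT SVC libraries (12.7 ± 0.707 CPM), a log2 difference of -3.40 (SE 0.18). These intervals and floors cover counting error only.

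The comparison of EAT with IAT SVCs asks how the stromal vascular cells of the 2 depots differ. In this fraction, 1229 genes were higher and 1085 lower in EAT, 2314 of 15813 in all, and 294 and 124 of them were at least 4-fold apart. With DESeq2's size factors the balance turned, to 1171 higher and 1198 lower. Of the 1880 SVC genes, 269 were higher and 369 lower in EAT, with a median log2 difference of -0.16 (quartiles -0.70 and 0.46) and a camera adjusted p of 0.239. Of the 956 adipocyte genes, 80 were higher and 80 lower, with a median near 0. With the class drawn anew each time, the 369 became 224 without IAT SVC replicate 2, 245 without EAT SVC replicate 3 and 567 without EAT adipocyte replicate 2. In EAT SVCs, 9 genes reached 1 CPM in all 3 libraries with no count in any IAT SVC library, and 1 gene did the reverse. The number of genes called in SVCs changed with the libraries that were fitted: 4964 genes passed when only the 6 SVC libraries were fitted, and 4747 without EAT adipocyte replicate 2. It fell to 1301 without IAT SVC replicate 2, to 1439 without EAT SVC replicate 1 and to 1520 without EAT SVC replicate 3. Each of these falls also took a library out of a compared group, so the spread was not separated from the lost replicate.

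The depot differences of the 2 fractions went together. Among the genes called in both, 695 were higher in EAT in both fractions, against 265 for independent lists, and 561 were lower in both, against 197. Another 47 were higher in EAT adipocytes and lower in EAT SVCs, and 130 the reverse. Thus 87.6% of 1433 genes went the same way. The 1256 genes that agreed in direction became 737 without IAT SVC replicate 2, 837 without EAT SVC replicate 1 and 2551 without EAT adipocyte replicate 2, and the 177 that did not became 101, 104 and 534, and 116 without EAT SVC replicate 3. Across all genes the log2 depot differences correlated at r = 0.475, with r = 0.663 for SVC genes, 0.447 for other genes and 0.217 for adipocyte genes. The comparisons share no library, but they do share each gene's spread from the joint fit, so their calls are not independent.

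**Figure D3:**
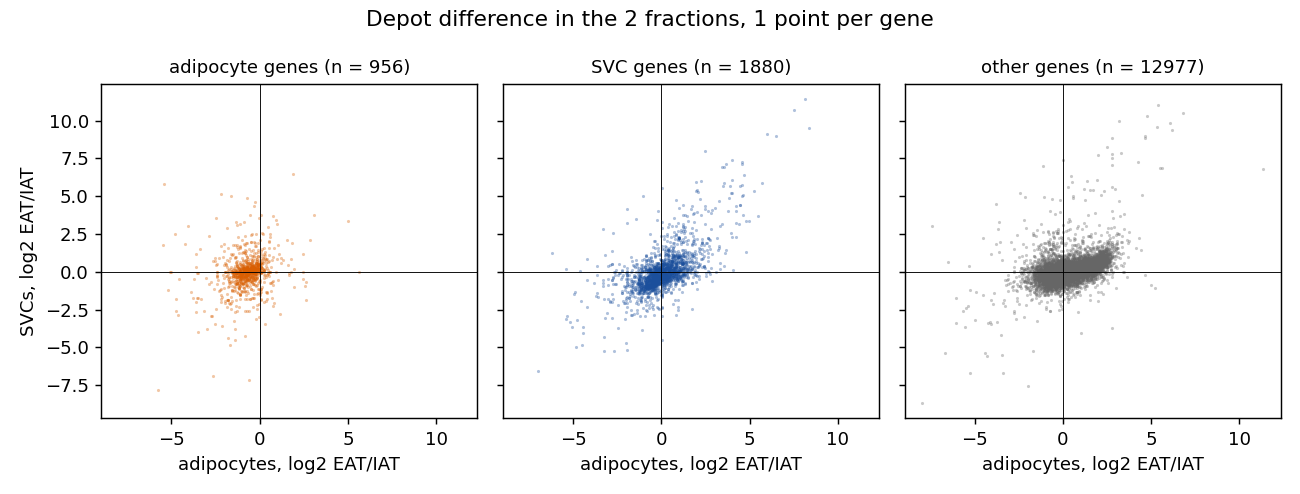
Log2 EAT to IAT difference of each gene in adipocytes (horizontal) and SVCs (vertical), by class. The SVC genes lie along a diagonal (r = 0.663), while the adipocyte genes lie mostly left of 0 in adipocytes and around 0 in SVCs (r = 0.217).

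Whether the depot difference itself differed between the fractions was tested with the depot by fraction interaction. It passed for 2867 genes, with 1640 more positive in adipocytes and 1227 more negative. Of these, 2023 had a depot difference in adipocytes and not in SVCs, 261 in SVCs and not in adipocytes, 177 had opposite differences, 332 differed in the same direction by unequal amounts, and 74 passed neither comparison. Of the 956 adipocyte genes, 267 had a more negative and 19 a more positive difference in adipocytes, with a median of -0.66 (camera adjusted p = 5.45e-18, and adjusted p = 0.168 with an estimated correlation). Among SVC genes 100 were more positive and 65 more negative. With DESeq2's size factors in place of TMM, 1311 genes were more positive and 1528 more negative. Without EAT adipocyte replicate 2, 5876 genes passed.

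EAT adipocyte replicate 2 stood apart along gene length. Relative to the other 2 EAT adipocyte libraries, the median log2 difference was 1.00 in the length decile of the shortest genes (median 811 bases) and -0.92 in that of the longest (median 6754 bases). In every library of the other 3 groups, these values lay between -0.11 and 0.08. Its effective length, weighted by abundance, was 1339 bases, against 1830 and 1813 in replicates 1 and 3. The levels of this library enter the depot difference in adipocytes, the fraction difference in EAT and the interaction. They also enter the mean over depots that defines the classes. Through the joint fit the library enters the spread used in all 5 comparisons. When it was left out, 4747 genes passed for the depot difference in SVCs and 12668 for the fraction difference in IAT. Without it, 644 of 884 adipocyte genes were lower in EAT adipocytes.

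**Figure D4:**
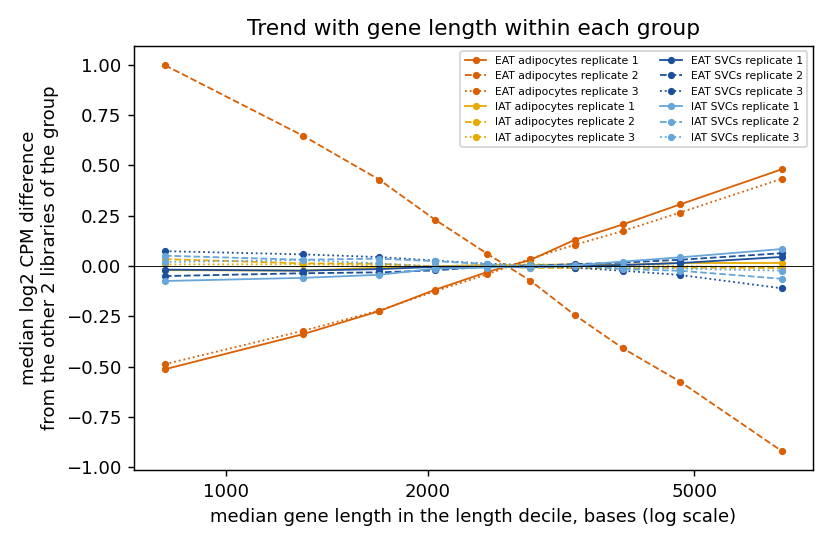
Median log2 CPM difference of each library from the other 2 of its group, by decile of gene length in bases (log axis). EAT adipocyte replicate 2 runs from 1.00 at the shortest genes to -0.92 at the longest, and the mirror trends of replicates 1 and 3 arise because replicate 2 is among the libraries they are set against.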

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

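Of the tests below, those on a mislabelled library, on the SVC RNA in EAT adipocyte replicate 2 and on the lower adipocyte genes were chosen only after the result was seen. Those on the length trend, on carry-over and on other splits of the libraries were set down before.

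The depot difference differed between adipocytes and SVCs for 2867 genes by the interaction test. The adipocyte genes had a median interaction of -0.66 log2. As a set they passed camera with the preset correlation (adjusted p = 5.45e-18) but not with an estimated one (adjusted p = 0.168). The gene uc008plc.1 had an interaction of -2.68 (SE 0.29, adjusted p = 0.000199, edgeR), being lower in EAT in 3 of 3 libraries of each fraction. Of 60 splits of the 12 libraries, the real one included, 4 gave at least as many genes, with 4844 as the highest of the others, so chance was not excluded for the count by this test. The drawn splits mix the fractions, so their interaction can carry the difference between adipocytes and SVCs. Grouped by that mixing after the counts were seen, the 20 that balanced the fractions gave at most 668 genes, the 25 with an imbalance of 2 libraries gave 0, and the 14 with an imbalance of 4 held all 3 others with as many genes but had a median of 0. Whether the mixing sets the count was not tested.

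EAT adipocyte replicate 2 stood apart from replicates 1 and 3. The median absolute log2 difference from them was 3.17 times that between replicates 1 and 3, and 1.98 times (1.84 and 2.12 for each) after a smooth trend with gene length was taken out. A length trend may thus account for part of the distance, and what remains lies between the bounds set for and against it as the whole cause. A mislabelled library was tested in 2 ways. By correlation, the lowest r with its own group exceeded the highest with another group by 0.0164, short of the bound of 0.02. A second test was added because the first left the matter open. It took genes at least 4-fold apart (adjusted p below 0.05, edgeR) in a fit without replicate 2. Of 1079 such genes between the adipocyte groups, 81.1% lay nearer to replicates 1 and 3, just past a bound of 80%. Of 2489 such genes between EAT adipocytes and EAT SVCs, 93.7% lay nearer to them. The library held 308 counts of uc009tsq.1, of which the IAT adipocytes had 0. That gene was chosen for being higher in every EAT adipocyte library, this library included, so its count has no bearing on a swap. On PC2 the library lay beyond replicates 1 and 3 (57.7 and 50.4), on the side away from the IAT adipocytes (-37.1 to -59.0). Together with the percentages this argues against a swap, although the correlation left the matter open. On PC1 the library stood at 111, level with the IAT adipocytes (109 to 118) and above replicates 1 and 3 (70.6 and 76.0). Its r with the SVC libraries was 0.784 to 0.813, against 0.843 to 0.881 for replicates 1 and 3. These values were not corrected for the length trend, and less SVC RNA could have this effect. After the length correction the SVC genes went both ways, with a median deviation of -0.045 log2 (quartiles -0.64 and 0.43), so a different share of SVC RNA stays open, and no biological explanation was tested.

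Of the 956 adipocyte genes, 494 were lower in EAT adipocytes, 22 were higher and 440 did not pass the test. As the whole cause, dilution by SVC RNA would need genes of the SVC fraction to stand at 0.478 of their EAT SVC level in EAT adipocytes. This was set against 1730 genes at least 4-fold higher in SVCs in a fit to the 6 IAT libraries alone. In the mean of the EAT adipocyte libraries, their median ratio was 0.182 with an upper quartile of 0.307, and 11.7% reached 0.478. In IAT, the depot in which these genes were chosen, the median ratio was 0.145. The EAT values argue against even dilution as the whole cause in the mean of the EAT adipocyte libraries. Dilution as a part of the cause was not tested. Dilution in single libraries was not tested, although replicates 1 and 3 (70.6 and 76.0) lay nearer to the SVCs on PC1 than replicate 2 (111). Dilution by a subset of SVCs was not tested either. The library that stood apart is argued against by the median without it, -0.96, over the 884 adipocyte genes drawn anew in that fit. The median was closest to 0 without EAT adipocyte replicate 1, at -0.48, over 1084 genes drawn anew. A scaling moves all genes alike, so it is argued against as the cause of the gap of -0.77 between the medians of adipocyte genes and other genes (0.06), the adipocyte genes' upper quartile of -0.25 lying below the latter. Whether adipocyte genes are lower or the others higher per cell stays open: the median was -0.71 or lower under each of 3 scalings, but these move the median of all genes by 0.167 at most. A lower level of adipocyte genes in EAT adipocytes may be a depot difference, as a hypothesis found and tested on the same libraries, which a camera test with an estimated correlation does not place apart from other genes (adjusted p = 0.112).

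Depot differences went the same way in the 2 fractions. RNA carried evenly from SVCs into the adipocyte fraction could supply part of the adipocyte difference. Its median share was 0.222 (quartiles 0.166 and 0.358) for 287 SVC genes and 0.0134 for 969 genes that are not SVC genes. Here carry-over was set at the 5th percentile of the SVC genes' ratio of adipocyte to SVC level (2.72% in EAT, 2.98% in IAT). Even carry-over would put a floor under every gene's ratio, so a low percentile was taken. The median ratios were higher (14.8% in EAT, 14.5% in IAT), and the shares at those settings were not computed. Carry-over of a subset of SVCs that differs from the whole fraction was not tested and stays open, as does a difference between the depots that both fractions share.

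With 3 libraries against 3 there are 10 splits, too few for a share below 0.05. The real split was the 1 of 10 with as many genes in each comparison: 6283 genes for the depot difference in adipocytes (highest other 0), 2314 for that in SVCs (0), 9876 for the fraction difference in EAT (1) and 11070 for that in IAT (0). Among the 4 splits that part all 3 numbered pairs, the highest other count was 0 in SVCs and 0 in IAT. For the fraction difference in the mean of both depots, 11866 genes passed. Of 60 splits only the real 1 gave as many, with 14 as the highest other. So high a count was thus rare among random labellings of all 12 libraries. The drawn groups mix adipocytes with SVCs, which can widen their spread and lower their counts, so chance is not called excluded.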

How the results depend on the processing

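Library weights, the length correction, the fit without the 10 most counted genes, and fits to 2 groups with the block or without EAT adipocyte replicate 2 were chosen after seeing the data. There were 30 results and 657 alternative values. No called log2 difference of a named gene changed sign. Nor did the median depot difference of adipocyte genes in adipocytes, the only class median recomputed. Of the values, 611 were counted as unchanged. Called differences of genes had to keep their direction and their side of the threshold. For differences that did not pass in the main fit, a change of sign also counted as unchanged. Shares had to stay within their binomial interval, the median within its quartiles and counts within 1.5 times. The cause was not tested for the other values unless stated. The gene lists and the setting without mitochondrial genes were not run, as genes have no symbols here.

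The interactions of uc008qql.1 (0.69) and uc029xfx.1 (-0.15), which did not pass the test, did change sign, to -0.55 without EAT adipocyte replicate 1 and to 0.23 without EAT adipocyte replicate 2.

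With only the libraries of the 2 groups, 4056 genes passed in adipocytes and 4964 in SVCs. With library weights, which gave EAT adipocyte replicate 2 a weight of 0.0602, 5757 passed in SVCs and 5999 in the interaction. With the 2 SVC groups alone and the replicate block 5799 passed. Each of these moved the count by over 1.5 times, and library weights also gave 2964 genes that went the same way in both fractions and 660 SVC genes lower in EAT SVCs. Leaving out 1 library gave 4993 to 8574 genes for the depot difference in adipocytes, 1301 to 4747 in SVCs, 8779 to 10611 for the fraction difference in EAT, 10111 to 12668 in IAT and 1946 to 5876 for the interaction, each highest value without EAT adipocyte replicate 2. The share of SVC genes among genes higher in EAT adipocytes was 6.29% with DESeq2's size factors, 8.61% with library size alone, 22.8% at the 2-fold definition, 6.24% with library weights, and 6.03% to 8.18% leaving out 1 library.

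The replicate block in the fit of all libraries gave 6475, 2505, 10065, 11201 and 3042 genes for the depot difference in adipocytes, that in SVCs, the fraction difference in EAT, that in IAT and the interaction, each within 1.5 times of the value without it, and it ended no call of the 4 named genes. DESeq2's size factors moved the median log2 difference of all genes from 0.02 to -0.11 in adipocytes between depots and from -0.24 to -0.09 between fractions in IAT, and library size alone moved that of IAT to -0.44 and that of EAT from -0.04 to -0.21. Depth limits genes near 3 counts, such as uc008qql.1 in EAT, whose fold rests on few counts.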

Other observations

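Across the tested genes, the log2 fold changes went with gene length by a rank correlation of -0.319 for the fraction difference in EAT, -0.181 for that in IAT, -0.171 for the depot difference in adipocytes, -0.144 for the interaction and -0.08 for the depot difference in SVCs. Genes are not independent replicates. EAT adipocyte replicate 2 is part of 3 of these 5 comparisons and not of the fraction difference in IAT or the depot difference in SVCs. The most abundant single gene took 3.35%, 2.16% and 3.27% of the counts in the IAT adipocyte libraries, 1.28%, 1.49% and 1.62% in the EAT adipocyte libraries, and 1.18% to 2.07% in the SVC libraries.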
